A study of Mus musculus with 6 samples.

How the data were processed

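Total RNA from mouse liver was used. Per the labels' protocols, it was extracted with a column kit and 1.3 ug entered library preparation with a SMARTER mRNA-Seq kit. The submitters' processing notes name the builds GRCm38 and mm10. The aligner, the counting tool, their versions and the use of strand are not given in the sources used here. The authors deposited a table of whole-number read counts per gene and a table of FPKM values for the same 6 libraries. Tested on the files, the deposited FPKM values equal the counts divided by 1 fixed length per gene and the column total, for 18913 of the 18913 genes with a count in at least 2 libraries (relative tolerance 1e-05). Total counts per library were 32826493 to 41102844, so that 3 counts, taken as the floor, correspond to 0.073 to 0.0914 CPM. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom 41.9 to 132.2), so each library was counted as 1 sample. Each library held 2120 to 3044 counts of Ddx3y and 0 to 9 of Xist.

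Groups were taken from the labels, 3 libraries each. Counts were tested with edgeR 4.0.16 in R 4.3.3, with the filterByExpr filter, TMM scaling and the quasi-likelihood test with the defaults of that version (legacy = TRUE), for DOX against PBS, without a block. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors were taken from the quasi-likelihood F statistic, and CPM are TMM-scaled. For single values, exact two-sided permutation tests over the 3 against 3 libraries were used, whose smallest p is 0.1. Before the data were examined, 37 gene lists of pathways, cell types and RNA quality were fixed. Of their 891 entries, 54 were not matched in the table, among them Arntl, which stands there as Bmal1, a synonym in the reference. Of the lists, 36 with at least 3 tested members were tested with camera (limma 3.58.1, inter-gene correlation 0.01, log2 CPM with a prior count of 2), and again with the correlation estimated and with fry. The list of exocrine pancreas genes had 2 tested members and was not tested. Coordinates are from the reference annotation of GRCm38.

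The genes named in the text follow a rule written before the data were examined. It takes a fixed set of focal genes and up to 10 genes per direction of smallest p with an adjusted p under 0.05, a log2 fold change of at least 1 in size, a mean of at least 1 CPM and no overlap of the groups. It adds 2 to 4 members of smallest p from each list discussed. Where fewer than 3 genes passed in a direction, those of smallest p were named as not passing.

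The procedure was tested on simulated counts for DOX against PBS, drawn from the means and library sizes of these libraries. Of 100 genes changed 2-fold, edgeR recovered 61%, and of 100 changed 4-fold, 91%. Of its calls, 11.1% were genes left unchanged, against 21.8% for DESeq2. The simulated genes varied independently of each other, and edgeR made 171 calls there, against 4 in the real libraries. These shares are therefore not the power of the real comparison. Alternatives were other scalings (RLE, library size only), DESeq2 1.42.0, limma-voom, other filters, a minimum log2 fold change of 0.5, the replicate number as a block, leaving out each library, and limma on log2 of the FPKM values plus 1 or 0.1. Chosen after the data were seen were a fit without Alb, a robust fit, the quasi-likelihood fit with legacy = FALSE, and the list test with Bmal1 matched. The values of 1 gene that the rule selects are not reported here.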

Results

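RNA from mouse liver was sequenced in 6 libraries, 3 labelled PBS and 3 labelled DOX. All 6 carry the same genotype label, a Buche knock-in in hepatocytes with Alb-Cre, and the same label of BDL treatment. BDL usually stands for bile duct ligation in mouse liver studies, although the labels do not spell it out, and neither DOX nor S10D is explained there. The deposited design text describes overexpression of butyrylcholinesterase in hepatocytes, and the series title concerns its effect on hepatic stellate cells through muscarinic signalling. The comparison was therefore DOX against PBS. Total gene counts per library ranged from 32826493 to 41102844, and 13725 of the 20914 listed genes were tested. The labels do not state that the libraries came from separate animals, so the p-values measure the spread between these libraries, which may be technical in part.

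Bche, the gene of butyrylcholinesterase (chromosome 3, 73635805 to 73708436 in GRCm38, protein coding), was the first gene examined. It stood at 210.6 ± 29.7 CPM (TMM-scaled read counts relative to library size) in PBS and 670.6 ± 268.9 in DOX (SD, n = 3 each). All 3 DOX libraries (447.5 to 969.2 CPM) lay above all 3 PBS libraries (192.8 to 244.9 CPM). The log2 fold change was 1.67 (SE 0.27), or 3.18-fold, with a 95% interval of 2.08 to 4.88-fold. The sources used here do not state whether the overexpressed sequence is the mouse one, and counts on the mouse gene could miss part of another, so the ratio is that of mouse Bche counts only. This did not pass the threshold across all genes (edgeR quasi-likelihood, adjusted p = 0.106), and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. Bche did pass with DESeq2 (adjusted p = 2.9e-08) and without the filter on low counts (adjusted p = 0.0057), within a range over all alternatives from 2.9e-08 to 0.406. Ache, the acetylcholinesterase gene, and the muscarinic receptor genes Chrm1, Chrm2, Chrm3 and Chrm4 were below the count filter, with group means of at most 0.276 CPM and at most 20 counts in a library. Their groups overlapped (exact two-sided permutation p = 0.4 to 0.7), which at such counts does not exclude a difference. Of the 8 tested genes on the list of cholinergic signalling, 1, which was Bche itself, was higher adjusted over the list alone and 0 over all genes. The list's median log2 fold change was 0.05 (camera adjusted p = 0.347). Chrna4, a nicotinic receptor subunit, had a log2 fold change of 1.45 (SE 0.52) that did not pass (adjusted p = 0.442).

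**Figure D1:**
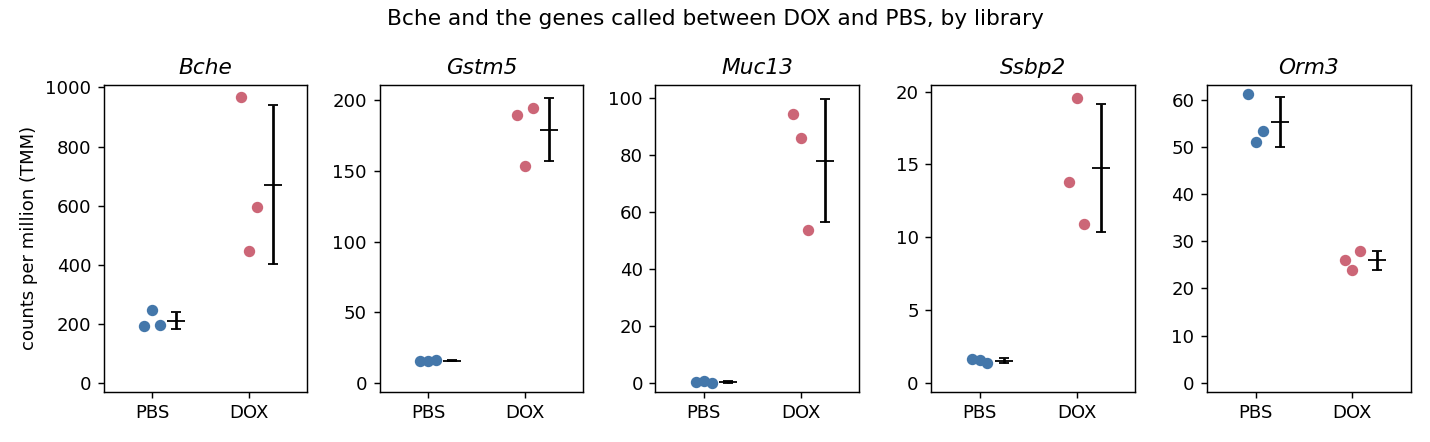
CPM (TMM-scaled, linear vertical axes) of Bche and of the 4 genes past the threshold in each library, grouped as PBS and DOX. Points are libraries and the black marks give the mean and SD of 3. In each panel the groups do not overlap, and DOX was higher for all but Orm3.

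Of the 13725 genes, 4 genes changed at an adjusted p of 0.05, with 3 higher and 1 lower in DOX (3 higher and 2 lower when scaled by library size only). Gstm5, a glutathione S-transferase of the mu class (chromosome 3, 107895854 to 107898685), rose from 15.6 ± 0.445 to 179.2 ± 22.5 CPM, a log2 fold change of 3.52 (SE 0.12, adjusted p = 1.78e-05). Muc13, a transmembrane mucin of epithelia (chromosome 16, 33794037 to 33819929), rose from 0.21 ± 0.238 to 78.1 ± 21.6 CPM. Its PBS libraries held 2 to 16 counts and its DOX libraries 1987 to 3543, and its log2 fold change was 8.62 (SE 0.47, adjusted p = 0.00034). Ssbp2, a single-stranded DNA binding protein (chromosome 13, 91460305 to 91706175), rose from 1.52 ± 0.159 to 14.8 ± 4.39 CPM, a log2 fold change of 3.28 (SE 0.24, adjusted p = 0.0028). Orm3, an orosomucoid of the acute phase family (chromosome 4, 63356069 to 63359506), fell from 55.3 ± 5.35 to 26.0 ± 1.96 CPM, a log2 fold change of -1.09 (SE 0.10, adjusted p = 0.014). Gstm5 and Orm3 belong to families of similar sequence whose reads the authors' counting could split, so their levels are uncertain in that respect. Next in the lower direction, and not past the threshold, came Wdfy1 (log2 fold change -0.79, SE 0.11) and Pros1, the protein S gene (log2 fold change -0.63, SE 0.09), both at an adjusted p of 0.105. Both passed with DESeq2 and without the filter on low counts, and Wdfy1 also when scaled by library size only. With limma-voom, Muc13 (adjusted p = 0.063) and Ssbp2 (adjusted p = 0.069) did not pass, and on the FPKM table neither did Ssbp2 (adjusted p = 0.178 to 0.229). Orm3 did not pass without PBS replicate 1 or 3, or without DOX replicate 1 or 2 (adjusted p = 0.068 to 0.080). DESeq2 called 176 genes, 128 higher and 48 lower, including all 4. At an unadjusted p under 0.05, edgeR gave 1359 genes, 690 higher and 669 lower, where 686 would be expected by chance. Of the other divisions of these libraries into 3 and 3, 1 gave 1188 such genes, and the rest 276 to 683. The groups did not overlap for 2314 genes, or 16.9%, where chance gives 10%.

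All 20 tested genes of fatty acid synthesis had a positive log2 fold change, with a median of 0.77, and 14 were higher adjusted over the list alone, against 0 over all genes. Among them, Pklr, the liver pyruvate kinase, went from 59.4 ± 15.9 to 151.2 ± 3.88 CPM (adjusted p = 0.105 over all genes). Fads2, a fatty acid desaturase, went from 207.3 ± 22.5 to 394.3 ± 31.6 CPM, and Acaca, the acetyl-CoA carboxylase of fatty acid synthesis, from 99.4 ± 16.6 to 183.2 ± 19.5 CPM. Genes of cholesterol synthesis had the same direction in all 25 members, with a median of 0.48, and 13 were higher adjusted over the list alone, against 0 over all genes. Nsdhl and Dhcr7, both enzymes of the late sterol pathway, had log2 fold changes of 0.82 (SE 0.12) and 0.66 (SE 0.10). The 5 genes named here did not pass over all genes in the edgeR fit, and passed with DESeq2 and without the filter. DESeq2 called 12 of the fatty acid and 7 of the cholesterol genes. By camera with a preset correlation of 0.01 both lists passed (adjusted p = 1.74e-16 and 6.26e-15). Neither passed with an estimated correlation (adjusted p = 0.835 for both), nor by fry (adjusted p = 0.329 and 0.523). Cytosolic ribosomal protein genes also had a positive log2 fold change in 32 of 32, with a median of 0.27, and their means lay between 8.26 and 8.44 log2 CPM in PBS and between 8.51 and 8.82 in DOX.

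Of the 36 lists tested, camera with the preset correlation called 12, of which 9 were higher and 3 lower, and none of the 12 calls held with an estimated correlation. Other divisions of the same 6 libraries into groups of 3 gave 11 to 20 called lists, so the number of calls did not set DOX and PBS apart from other groupings. Which lists were called in those divisions was not compared. Leaving out 1 library gave 9 to 16.

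Cytochrome P450 and drug metabolism genes had a median log2 fold change of 0.62, and 24 of 29 were positive, with 6 higher adjusted over the list alone and 0 over all genes. Cyp2c29 stood at 285.9 ± 47.0 CPM in PBS and 615.5 ± 226 in DOX, and Ces1d, a carboxylesterase, at 243.8 ± 25.2 and 440.8 ± 102. Neither passed over all genes, and both passed with DESeq2 and without the filter. DESeq2 called 5 members of the list higher and 1 lower. The lower one, Cyp2b9 (log2 fold change -4.92, SE 1.29, DESeq2 adjusted p = 0.019), was not among the genes tested with edgeR and lies outside the naming rule. The camera call (adjusted p = 2.16e-05) was lost with an estimated correlation (adjusted p = 0.835). DOX replicate 3 had the highest mean of this list, 8.06 log2 CPM, where the other 5 libraries lay between 6.93 and 7.39. Without it the median was 0.31. The list of bile acid synthesis and transport had a median of 0.24 with 1 member higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00031, adjusted p = 0.835 with an estimated correlation). Slco1b2, an organic anion transporter of the hepatocyte membrane, had a log2 fold change of 0.70 (SE 0.16), and Slc10a1, the bile acid uptake transporter, 0.77 (SE 0.22), and neither passed over all genes (adjusted p = 0.259 and 0.369), although both passed with DESeq2. Fgfr4 was lower (log2 fold change -0.42) and also passed only with DESeq2 (adjusted p = 0.025), which called 2 members of the list higher and 1 lower. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 141.5 ± 92.3 and 163.9 ± 21.2 CPM (adjusted p = 0.882). On the list of PPAR alpha and fatty acid oxidation, 2 of 28 genes were higher adjusted over the list alone, and the median was 0.23 (camera adjusted p = 0.00048, adjusted p = 0.908 with an estimated correlation). Fabp1, the liver fatty acid binding protein, stood at 11.9 ± 2.92 CPM in PBS and 90.3 ± 54.0 in DOX (adjusted p = 0.105), and passed with DESeq2, without the filter and without DOX replicate 2 (adjusted p = 0.030). The list of NRF2 oxidative stress response had a median of 0.30, with 26 of 28 positive and 0 higher adjusted over the list alone (camera adjusted p = 7.91e-05, adjusted p = 0.835 with an estimated correlation). Without DOX replicate 3, camera no longer called the bile acid, PPAR alpha or NRF2 list (adjusted p = 0.086, 0.062 and 0.075), and their medians were 0.12, 0.14 and 0.13. Without PBS replicate 1 it no longer called PPAR alpha (adjusted p = 0.109, median 0.13), whose median without PBS replicate 2 was 0.38.

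The stellate cell question of the series title was addressed by 3 lists. On the list of hepatic stellate cell activation, 0 of 21 genes changed adjusted over the list alone. The median log2 fold change was 0.12, while the mean of the list in log2 CPM was 3.14 ± 0.038 in PBS and 3.11 ± 0.515 in DOX (exact two-sided permutation p = 1, camera adjusted p = 0.747). Without DOX replicate 3 camera called this list higher (adjusted p = 0.0001, median 0.37), and without DOX replicate 1 the median was -0.08. Scaled by library size only, it was -0.01. Acta2, the smooth muscle actin of activated stellate cells, stood at 3.65 ± 0.711 CPM in PBS and 5.83 ± 3.14 in DOX (log2 fold change 0.67, SE 0.40, adjusted p = 0.609). Col1a1, a chain of type I collagen, had a log2 fold change of 0.45 (SE 0.43), and Timp1, an inhibitor of matrix proteases, 0.13 (SE 0.43). Spp1, the osteopontin gene, had a log2 fold change of -0.66 (SE 0.27) that did not pass either (adjusted p = 0.486). On the list of fibrillar collagen and extracellular matrix, 24 of 28 genes had a positive log2 fold change and 0 passed over the list alone (median 0.21, camera adjusted p = 0.347). Its mean in DOX replicate 3 was 3.80 log2 CPM, below all other libraries (4.11 to 5.05). Without that library camera called the list higher (adjusted p = 7.76e-11, median 0.53), and without DOX replicate 1 the median was -0.06. Camera also called it higher when scaled by library size only (adjusted p = 0.026) and on the FPKM table (adjusted p = 0.015). The quiescent stellate cell list had a median of 0.25 with 0 of 17 genes past the threshold over the list alone (camera adjusted p = 0.115), and its mean in PBS replicate 2 was 2.38 log2 CPM against 3.21 to 3.69 in the others. Camera called it higher without PBS replicate 3 (adjusted p = 0.0023), when scaled by library size only (adjusted p = 0.0084) and on the FPKM table (adjusted p = 0.032). Its median was 0.00 without PBS replicate 2 and 0.03 without DOX replicate 1. The 95% interval of the Acta2 log2 fold change spanned -0.25 to 1.59.

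**Figure D2:**
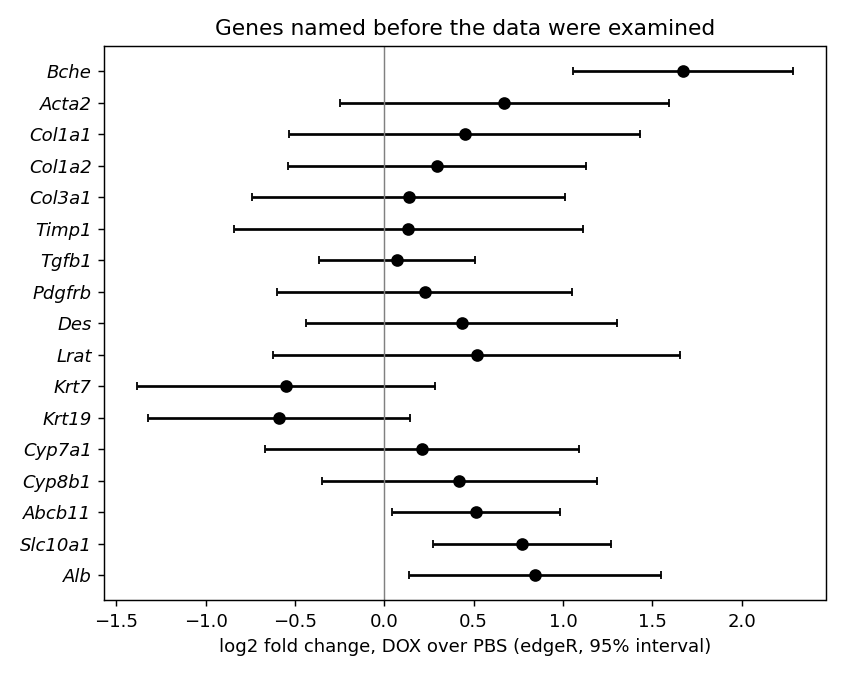
Log2 fold change of DOX over PBS (horizontal axis) with 95% intervals from edgeR, not adjusted for multiple tests, for the tested genes named before the data were examined. Bche had the highest value, 1.67, and none of these genes passed the threshold over all genes.

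Cholangiocyte genes had a negative log2 fold change in all 21 tested members, with a median of -0.64. Of these, 1 was lower adjusted over the list alone and 0 over all genes. Tspan8, a tetraspanin, stood at 13.6 ± 2.86 CPM in PBS and 7.71 ± 0.541 in DOX (passed with DESeq2, adjusted p = 0.0099), and Cftr, the chloride channel of the duct epithelium, at 2.93 ± 0.088 and 1.61 ± 0.247. Krt19 and Krt7, keratins of duct cells, had log2 fold changes of -0.59 (SE 0.32) and -0.55 (SE 0.37). The camera call (adjusted p = 3.01e-07) was lost with an estimated correlation (adjusted p = 0.835). Liver endothelial genes had a positive value in 24 of 26, with a median of 0.69 and 0 past the threshold over the list alone. Ptprb, an endothelial phosphatase, stood at 16.9 ± 9.10 and 36.0 ± 13.9 CPM, and Flt1, a receptor of vascular growth factors, at 4.36 ± 1.55 and 8.44 ± 2.15. The camera call (adjusted p = 4.26e-06) was lost with an estimated correlation (adjusted p = 0.835). PBS replicate 2 had the highest cholangiocyte mean (3.94 log2 CPM, others 2.57 to 3.22) and the lowest endothelial mean (1.91, others 2.85 to 3.68). Without it the medians were -0.32 and 0.35. Hepatocyte genes had a median of 0.08 (camera adjusted p = 0.080). Camera called them higher without the filter (adjusted p = 0.049), without PBS replicate 2 (adjusted p = 0.0055, median 0.16) and without DOX replicate 2 (adjusted p = 0.036). It also did so when scaled by library size only (adjusted p = 0.032), where the median was -0.05, and on the FPKM table the median was -0.06. Alb, the albumin gene, took 10.1% and 10.2% of counts in DOX replicates 1 and 3, against 4.87% to 6.09% in the other libraries, and did not pass (log2 fold change 0.84, SE 0.31, adjusted p = 0.457), although it did with DESeq2 (adjusted p = 0.018).

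**Figure D3:**
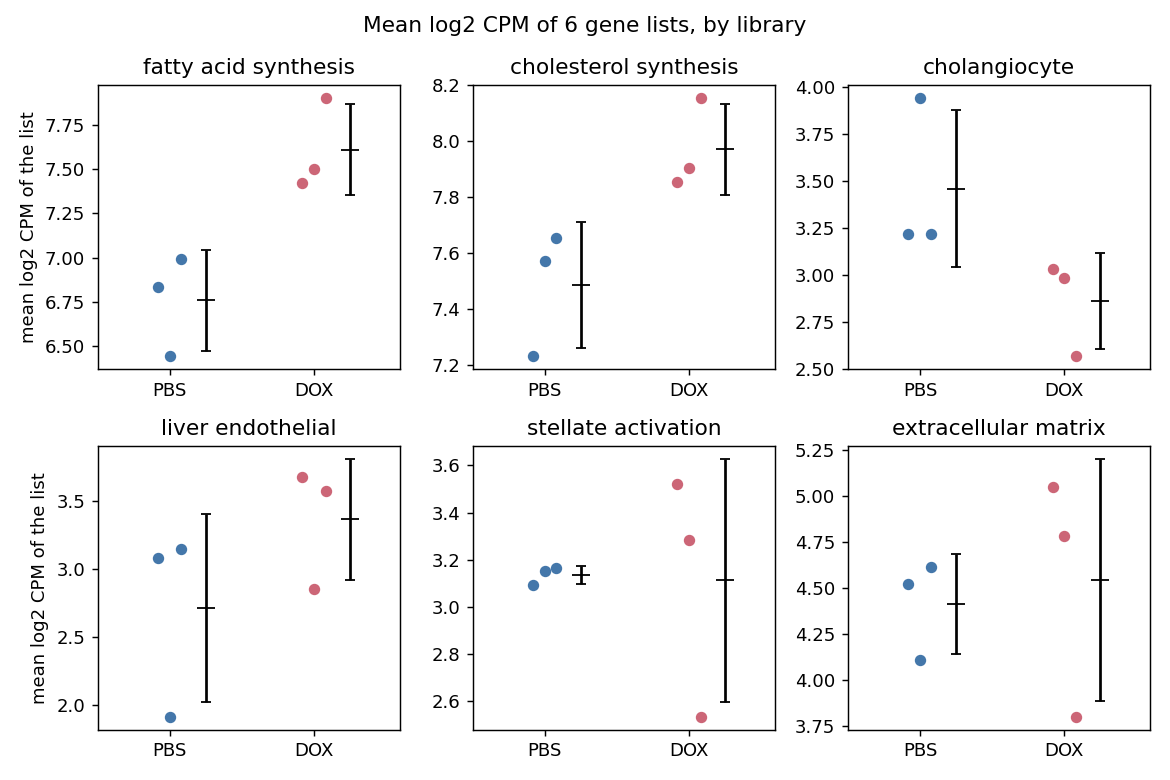
Mean log2 CPM of the tested members of 6 gene lists (vertical axes, not starting at 0) in each library, with the mean and SD of 3 libraries as black marks. The groups are apart for fatty acid synthesis, cholesterol synthesis and cholangiocyte genes, and overlap for endothelial, stellate activation and extracellular matrix genes.

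Acute phase genes had a median log2 fold change of -0.15. Of 26 genes, 1 was lower over all genes, which was Orm3, and Saa1, a serum amyloid A, stood at 535.8 ± 175 and 293.0 ± 193 CPM (adjusted p = 0.545). The camera call (adjusted p = 0.030) was lost with an estimated correlation (adjusted p = 0.908), and without PBS replicate 1 or 2 or DOX replicate 2 or 3 (highest adjusted p = 0.385). It was also lost when scaled by library size only (adjusted p = 0.132) and on the FPKM table (adjusted p = 0.086). Chemokine and cytokine genes had a median of -0.10 with 0 of 29 past the threshold over the list alone (camera adjusted p = 0.771). Macrophage genes had a median of 0.01 (camera adjusted p = 0.926), and neutrophil genes of -0.28 (camera adjusted p = 0.231). Camera called the macrophage list higher without DOX replicate 3 (adjusted p = 0.021). It called the neutrophil list lower without the filter (adjusted p = 0.026), without PBS replicate 2 (adjusted p = 0.0057) and without PBS replicate 3 (adjusted p = 0.020), while without PBS replicate 1 its median was -0.02.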

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

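The fits without Alb, with robust estimation and with legacy = FALSE were chosen after the data were seen, and each gave 4 genes changed. Matching Arntl to Bmal1, also chosen after, left 12 lists called. With legacy = FALSE the adjusted p of Bche was 0.0969. Bche kept its direction in each setting, with a log2 fold change of 1.69 with DESeq2 and 1.68 without the filter, the settings where it passed, and 1.32 to 1.90 when 1 library was left out. DESeq2 gave 176 genes changed, 128 higher and 48 lower, and no filter gave 61, 45 and 16. The 4 genes were shared with both. Limma-voom gave 2 genes changed, 1 higher. Library size alone gave 2 genes lower, and moved the median of all genes to -0.149. A minimum log2 fold change of 0.5 gave 0 lower. Leaving out 1 library gave 3 to 4 genes changed, 3 to 4 higher and 0 to 1 lower. The cause of these differences was not tested. Camera called 9 to 16 lists when 1 library was left out, and 0 lists were called with an estimated correlation or by fry. Without DOX replicate 3, the respiratory chain list reversed (adjusted p = 0.255, range 2.87e-06 to 0.812 when 1 library was left out), and the muscle list, whose direction by camera was lower (adjusted p = 0.926), was called higher (adjusted p = 0.0405, range 0.0405 to 0.791), while its median stayed positive (0.43, and 0.75 without that library). That median was negative only without DOX replicate 1 (-0.12). Of 97 named genes not called, 8 changed sign in at least 1 setting, among them Col3a1, Tgfb1 and Timp1 in 6 settings each.

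With the replicate block, 21 genes changed, 17 higher and 4 lower, among them Fabp1 (adjusted p = 0.015) and Pklr (adjusted p = 0.039), and 13 lists were called, p53 genes among them (lower, adjusted p = 0.037). Libraries of the same number had correlated deviations of 0.243, 0.185 and 0.024, and those of different numbers of -0.232 to 0.0746. This leaned toward a pairing for replicates 1 and 2, while PBS replicate 3 correlated best with DOX replicate 1. A pairing is thus not excluded. As the labels give the numbers no meaning, they were not used as a block in the main fit. Genes with few counts, such as the muscarinic receptors (floor 0.073 to 0.0914 CPM), are limited by depth.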

Other observations

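Of the cytosolic ribosomal protein genes, 0 passed the threshold over the list alone (camera adjusted p = 2.68e-14, adjusted p = 0.835 with an estimated correlation). Without DOX replicate 3 their median was 0.17. Immediate early genes had a median of -0.21 and 1 of 22 lower over the list alone (camera adjusted p = 0.013, adjusted p = 0.835 with an estimated correlation), and the call ended without PBS replicate 2 (adjusted p = 0.349), without DOX replicate 3 (adjusted p = 0.075) and when scaled by library size only (adjusted p = 0.067). Fos, a member, had a log2 fold change of -0.93 (SE 0.19, adjusted p = 0.216), and passed with DESeq2 (adjusted p = 0.0044). Nuclear respiratory chain genes had a median of 0.10 (camera adjusted p = 0.038, adjusted p = 0.96 with an estimated correlation). That call was lost when scaled by library size only (adjusted p = 0.121, median -0.04), on the FPKM table (adjusted p = 0.198, median -0.05), without PBS replicate 1 (adjusted p = 0.812, median 0.02) and without DOX replicate 3 (adjusted p = 0.255, median -0.05). Mitochondrially encoded transcripts had a median of 0.05 (camera adjusted p = 0.347), and were called higher without DOX replicate 1 (adjusted p = 0.0078) and without PBS replicate 2 (adjusted p = 0.024). Camera did not call the others. Their medians were 0.24 for T and NK cells (14 tested genes, with a mean of 0.564 CPM) and -0.40 for B and plasma cells (4 tested of 22 listed). They were 0.32 for erythrocytes (8 tested), -0.04 for adipocyte and mesothelial genes (11 tested) and 0.43 for muscle (5 tested). They were -0.09 for proliferation, -0.12 for interferon response, -0.13 for MHC class II, 0.00 for the unfolded protein response, 0.04 for ATF4 and -0.16 for p53. Mitochondrial translation had 0.03, the circadian clock -0.21, male-biased liver genes 0.18 and female-biased liver genes -0.04. Of the 24 lists that camera did not call, 17 had a median that changed sign when 1 library was left out, and 15 were called in at least 1 alternative. T and NK cells had -0.42 without DOX replicate 2, and erythrocytes -0.29 without DOX replicate 3. MHC class II genes had 0.17 without DOX replicate 3, and -0.65 without DOX replicate 2, where camera called them lower (adjusted p = 0.00039). Without DOX replicate 2 it also called erythrocyte genes higher (adjusted p = 0.014), and interferon response (adjusted p = 0.0046) and proliferation genes (adjusted p = 0.046) lower. Without PBS replicate 3 it called the unfolded protein response higher (adjusted p = 0.00062) and p53 genes lower (adjusted p = 0.029). Male-biased genes were called higher when scaled by library size only (adjusted p = 0.046), and muscle genes without DOX replicate 3 (adjusted p = 0.0405).

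In the patterns that follow, the test of neighbouring genes and the counts over other groupings were written before their results were seen, and the other tests were chosen after. The bounds for leaving out libraries, for the cell types and for the hepatocyte share were set again after first values were seen, so that a difference has to exceed the spread between libraries. Gstm5, Muc13 and Ssbp2 were higher in DOX. Reads of other Gstm genes counted as Gstm5 would keep its ratio to them alike, but the lowest DOX ratio was 2.37 times the highest PBS ratio. A change of the whole chromosome segment was argued against by the tested genes within 1 Mb, whose median plus SD reached at most 0.213 of each gene's own log2 fold change. A single library did not carry the difference, since the lowest DOX library was at least 6.67 times the highest PBS library. The rule that named these genes already required groups without overlap, so this adds only the size of the gap. The DOX treatment itself, the higher Bche and a difference in background between the animals stay open and untested, as all follow the groups.

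All tested members of the fatty acid and cholesterol synthesis lists had positive log2 fold changes, although 0 passed over all genes and the camera calls were lost with an estimated correlation (adjusted p = 0.835 for both). A larger share of hepatocyte RNA would raise hepatocyte genes as much, and their median plus SD was 0.427 with all libraries. The fatty acid median stayed above that sum by at least 0.154 with all libraries or without any 1 of them. So a hepatocyte share, as measured by this list alone, does not account for its size. The cholesterol median of 0.475 did not stay above the sum in each of these fits, with a lowest margin of -0.149, so there a hepatocyte share cannot be told apart. The bound depends on the list chosen, as cytochrome P450 and drug metabolism genes had a median of 0.62 and that list was not used for it. Leaving out any 1 library kept at least 0.722 of either median. A shift in the time of collection cannot be told apart, since the size of clock gene changes (median 0.234, median plus SD 0.525) lay between the list medians of 0.475 and 0.770 only with the SD added. Without Lpin1, which is also on the fatty acid list, the sum was 0.474, at the bound. Adjusted over the clock list alone, Cry1 was higher and Per2 lower. Bmal1, listed as Arntl and so not matched, had a log2 fold change of 0.59 (SE 0.12, adjusted p = 0.216) and passed with DESeq2 (adjusted p = 0.012). The treatment and the higher Bche, which follow the groups, were not tested apart.

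The median of cholangiocyte genes was negative and that of endothelial genes positive, with camera calls lost with an estimated correlation (adjusted p = 0.835 for both) and endothelial means that overlapped between the groups. Without PBS replicate 2 the medians were -0.323 and 0.347, close to 50% of their full size (0.502 and 0.507 of it). The cholangiocyte means of PBS replicates 1 and 3 (3.22 and 3.21 log2 CPM) still lay above all DOX libraries (2.57 to 3.03). The cholangiocyte difference among these libraries thus did not rest on PBS replicate 2 alone, although its part in it is not settled. The endothelial means of PBS replicates 1 and 3 (3.08 and 3.15) lay within the DOX range (2.85 to 3.68). There, this library alone as the source cannot be told apart from a difference of the groups. A different share of hepatocytes would move both lists the same way, but the medians lay 1.33 apart with opposite signs, also in 6 of 6 fits without 1 library. Per library, the difference of the lists differed by 1.25 between the groups, above its pooled SD of 0.888, but it overlapped between them. The endothelial mean lay below the cholangiocyte mean in DOX replicate 2 (2.85 against 2.98 log2 CPM), as in PBS replicate 3 (3.15 against 3.21). Without any 1 library the difference stayed at least 1.04 times its SD. For the genes of these 2 lists, the opposite signs argue against a hepatocyte share as the source of both shifts. With this overlap and the weight of PBS replicate 2, whether the groups differ in these lists stays open. The treatment, which follows the groups, was not tested apart from the weight of that library.

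With 10 splits of the 6 libraries into 3 and 3, a share under 0.05 cannot be reached. The real split gave 4 genes changed and the highest of the others 1, so that 1 split of 10 gave as many. For the lists called by camera with a preset correlation, the real split gave 12 and the highest of the others 20, and 9 of the 10 splits gave at least as many. On the first principal component (34.7% of the variance), PBS replicate 2 and DOX replicate 3 lay at the ends. The same component ordered the groups without overlap, with PBS at -40.1 to -5.99 and DOX at 0.841 to 37.6.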
